A study of Homo sapiens with 13 samples.

How the data were processed

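Per the labels, human plasmacytoid dendritic cells (pDCs) were enriched with magnetic beads and sorted by flow cytometry as cells negative for lineage markers including CD3, CD14 and CD1c and positive for CD123, ILT3 and BDCA2. Single cells were then profiled in 13 libraries with the 10x Genomics 3' chemistry, per the labels. 7 libraries each hold 1 tissue (2 of blood, 2 of thymus, 3 of tonsil). The labels place tonsil libraries 1 and 2 in batch 1 and tonsil library 3 and blood library 2 in batch 2, and give no batch for the others. 6 libraries each hold several tissues of 1 donor, marked by antibody hashtags whose names in the deposited feature lists give blood, thymus or lymph node. In 2 of the 6 donor libraries, those of donors 5 and 6, the tissues named by the label and by the hashtags differ. There the hashtags were used, and an alternative left those donors out.

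The deposited matrices hold counts: UMI counts per gene and cell barcode, with no normalization. Per the file headers they were made with Cell Ranger 5.0.1 (5 sorted libraries), 6.1.1 (tonsil library 3 and blood library 2), 7.1.0 (donors 1 to 3) and 7.2.0 (donors 4 to 6), and per the labels on GRCh38. The submitters' processing notes name Seurat 4.0, and the settings of any further filtering by the authors are not given in the sources used here. All values were whole numbers, and no pair of libraries of a group agreed within sampling noise (chi-square per gene 7.08 to 320.3), so none was counted as a duplicate. Where the labels name no separate donors for the sorted libraries, p-values measure only the spread between these samples, which may be technical.

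Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were used. Scrublet, run through scanpy 1.11.5, ranked cells per library, and the highest 0.8% per 1000 barcodes were removed. Hashtags were called with Seurat 5.3.0 HTODemux (positive quantile 0.99, with 1 added to every hashtag count), and hashtag multiplets were removed. The share of cells without a call ranged from 0.415% (donor 4) to 70.3% (donor 5). The alternatives were MULTIseqDemux and a ratio rule (top hashtag with at least 100 UMIs and 5 times the next).

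Cells of all libraries were clustered together on 30 principal components of the variable genes (2500 before cycling, immunoglobulin, T cell receptor, Y-linked and XIST genes were left out) with 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2), without integration. This gave 33 clusters. Of 14 fixed marker lists, those of AXL SIGLEC6, mature and conventional dendritic cells did not compete as lineages. No cluster could therefore be named mature or conventional dendritic cell. From the other lists, a cluster took the lineage whose markers were on average found in the largest share of its cells, if at least 3 of them were found in at least 25% of cells. A cluster was called AXL SIGLEC6 dendritic cell-like if its markers were found on average in at least 50% of cells and led its top 10 genes, and monocyte-like if 3 monocyte markers did. Clusters of under 20 cells, and those with a depth under 0.333 times the usual one and 0 own markers among their top 10 genes, stayed unnamed. These limits were set after the clusters were seen. Unnamed cells made up 0 to 5.26% of a library. The classes rest on clusters that differ between libraries: 99.9% of the pDC-like cells of blood library 1 lay in 1 cluster and 98.8% of those of thymus library 1 in a different one. 4 pDC-like clusters had the B cell gene BLK and, like most others, 0 pDC markers among their top 10 genes over other lineages. On average pDC markers were found in 65.8 to 97.6% of their cells and B cell markers in 14.2 to 18.3%. No count left them out.

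UMIs of pDC-like cells were summed per sorted library or per donor and tissue, with at least 30 cells per sum. This gave 7 sorted and 16 donor sums. Each set was fitted once with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr), with donor as a block in the donors and no block in the sorted libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its size divided by the square root of F. Donors pair the tissues by design, and the deviations of same-donor sums from their tissue means correlated at 0.455 to 0.733 over 6771 genes.

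On simulated data with the same samples, 100 genes changed 2-fold or 4-fold were tested. edgeR recovered 78% and 97% for thymus against blood in donors, 71% and 98% for lymph node against blood, and 59% and 90% for lymph node against thymus. In the sorted libraries it recovered 6% and 59% (tonsil and blood), 8% and 69% (tonsil and thymus) and 2% and 65% (thymus and blood), and it called 6 to 8 unchanged genes in each comparison (3.31 to 9.72% of its calls). DESeq2 called 15 to 49 unchanged genes (8.24 to 32.1% of its calls), so its larger counts on the real data may hold more false calls.

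18 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided), with an estimated correlation and with fry. The lists are pDC identity, S phase, G2/M phase, type I and III interferons, interferon-stimulated genes, AXL SIGLEC6 dendritic cell, activation and maturation, trafficking receptors, nucleic acid sensing, NF-kB and inflammatory response, immediate early and dissociation stress, MHC class II presentation, lymphoid precursor, oxidative phosphorylation, glycolysis, unfolded protein response, cytosolic ribosomal proteins and glucocorticoid response. Shares of cells were compared with exact permutation tests, by sign flips over donors or by regrouping sorted libraries, two-sided. Cells were thinned to 2000 UMIs before cycling genes (20) or AXL SIGLEC6 genes (9) were counted, and 3 genes were needed.

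The rule for named genes took the 10 largest rises and 10 largest falls among called genes with at least 20 CPM in the higher group and the same direction in every pair (donors) or no overlap (sorted). It added up to 4 called members per list and 10 genes named always. It names 93, 73, 10, 50, 49 and 63 genes in the 6 comparisons, in the order of the report. The text describes 44, 30, 10, 32, 33 and 33 of these, picked after their values were seen. Y-linked genes, immunoglobulin and T cell receptor segments and classical HLA genes were left out of the text, as were some genes near 0 in a group and some with close paralogs, such as CCL3 and CCL4.

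Samples, tests, gene lists and most alternatives were fixed before the data were examined. Alternatives for the tests were RLE factors, DESeq2 1.42.0, no low-count filter, only the 2 groups in the fit, a stricter cell filter (1000 genes, 5% mitochondrial), Scrublet-ranked cells kept, all filtered cells, no cycling cells, at least 100 cells per sum, the other hashtag calls, no block or a block, and each sample left out. Shares were also computed at other thinning depths and numbers of genes. Gene positions are from GENCODE 29. Other tools were R 4.3.3, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.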

Results

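Plasmacytoid dendritic cells (pDCs), immune cells that secrete large amounts of type I interferon after sensing viral nucleic acids, were sorted from human tissues and profiled by droplet single-cell RNA sequencing in 13 libraries. The series title names differences of pDCs between tissues and a cycling subset as the subject. 7 libraries each held pDCs of a single tissue, with 2 libraries of blood, 2 of thymus and 3 of tonsil, and are called the sorted libraries here. The other 6 libraries each pooled the tissues of 1 donor, with antibody-linked barcodes (hashtags) marking cells from blood, thymus and, in donors 1, 2, 4 and 6, a lymph node near the thymus. Thymus is the organ where T cells mature, and tonsil and lymph node are secondary lymphoid tissues.

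The sorted blood libraries held 49715073 UMIs in 3244 barcodes and 64639049 UMIs in 5960 barcodes. The sorted thymus libraries held 80904335 UMIs in 8502 barcodes and 17589023 UMIs in 1499 barcodes. The 3 tonsil libraries held 63754248, 54360632 and 63661000 UMIs in 6263, 4952 and 6249 barcodes. Donor libraries 1 to 6 held 116109003, 141669661, 157209435, 187616008, 123933541 and 150019393 UMIs in 7421, 7498, 13184, 16533, 11513 and 9601 barcodes. Comparisons between tissues used UMI counts summed over the pDC-like cells of each sorted library (1335 to 7493 cells, 16977463 to 72509326 UMIs) or of each donor and tissue (112 to 7960 cells, 840716 to 91434534 UMIs). Levels below are means of normalized counts (CPM) ± SD over these sums, and log2 fold changes come from the edgeR fit and are followed by ± SE. Genome positions are on GRCh38.

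In the 6 donors, the comparison of thymus with blood asked how pDCs differ between a tissue and the circulation of the same person. Thymic pDCs had higher levels of cell cycle genes and of genes induced by interferon, and lower levels of a set that included SORL1, ATP10A and STK32B. MKI67, a nuclear protein of proliferating cells (ENSG00000148773, chromosome 10, 128096659 to 128126385), stood at 43.7 ± 24.4 against 1.73 ± 1.87 CPM (SD, n = 6 donors) and was 27.4-fold higher in thymus (log2 fold change 4.77 ± 0.63, adjusted p = 6.6e-05). The interferon-induced mitochondrial protein IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218) was 20.5-fold higher, at 48.1 ± 12.5 against 3.07 ± 3.16 CPM (log2 fold change 4.36 ± 0.61, adjusted p = 9.8e-05). In the other direction, the kinase gene STK32B (ENSG00000152953, chromosome 4, 5051442 to 5500998) was 10.7-fold lower, at 6.61 ± 3.42 against 63.1 ± 16.0 CPM (log2 fold change -3.42 ± 0.33, adjusted p = 1.2e-05). All 3 genes moved the same way in 6 of 6 donors.

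All 29 of 29 interferon-stimulated genes rose in thymus (median log2 fold change 3.12, 29 up and 0 down when adjusted over the list alone, camera adjusted p = 2.9e-12, and adjusted p = 0.33 with an estimated correlation). USP18, which removes the ubiquitin-like protein ISG15 from its targets, stood at 71.4 ± 8.27 against 7.07 ± 7.51 CPM. RSAD2, which encodes the antiviral enzyme viperin, had a log2 fold change of 3.96 ± 0.56, and the RNA sensor gene IFIH1 one of 2.48 ± 0.31. IFITM1, a membrane protein that restricts virus entry, rose by 4.97 ± 0.73 and IFI27 by 4.56 ± 0.65, while TRIM22 rose by 0.86 ± 0.10. The interferon-inducible nuclear protein gene MNDA, which is outside the list, stood at 106 ± 36.3 against 8.41 ± 10.7 CPM. None of the type I and III interferon genes themselves was measured in the donor sums, since 0 of the list passed the count filter.

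Among G2/M phase genes, 29 of 30 measured members rose, 0 fell and 1 did not pass the test (29 up and 0 down when adjusted over the list alone), with a median of 2.43. The G2/M phase list had a camera adjusted p of 5.9e-09 (adjusted p = 0.33 with an estimated correlation). UBE2C, a ubiquitin-conjugating enzyme of mitosis, rose by 4.67 ± 0.75 and TOP2A, which untangles DNA before chromosomes separate, by 3.26 ± 0.54. Among S phase genes, 18 of 25 measured members rose, 1 fell and 6 did not pass the test (19 up and 1 down when adjusted over the list alone), with a median of 0.74. The S phase list had a camera adjusted p of 0.00014 (adjusted p = 0.39 with an estimated correlation). RRM2 and TYMS, enzymes that make DNA building blocks, rose by 4.51 ± 0.54 and 3.40 ± 0.47. Markers of other cell types moved as well within the pDC-like sums. 7 of 9 measured T cell or thymocyte markers rose (summed level 476 against 398 CPM), as did 3 of 6 B cell markers (532 against 322 CPM), while 4 of 4 platelet markers fell (28.2 against 48.8 CPM). NK cell markers were at 51.8 against 24.6 CPM (2 of 4 rose), monocyte markers at 11.1 against 2.32 (1 of 2 rose) and stromal markers at 131 against 92.9 (2 of 4 rose). Of conventional dendritic cell markers 2 rose and 1 fell (35.6 against 61.5 CPM).

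Immediate early and dissociation stress genes, which respond within minutes to stimulation or handling, were also higher in thymus: 22 of 23 measured members rose, 0 fell and 1 did not pass the test (22 up and 0 down when adjusted over the list alone), with a median of 1.42. The stress gene list had a camera adjusted p of 1.9e-10 (adjusted p = 0.18 with an estimated correlation). JUN, a subunit of the AP-1 transcription factor, rose by 2.67 ± 0.31 and the chaperone gene HSP90AA1 by 0.70 ± 0.069. In the NF-kB and inflammatory list 12 of 15 measured members rose, 0 fell and 3 did not pass the test (12 up and 0 down when adjusted over the list alone) (camera adjusted p = 5.0e-06, and adjusted p = 0.33 with an estimated correlation), and in the activation and maturation list 12 of 15 measured members rose, 1 fell and 2 did not pass the test (12 up and 1 down when adjusted over the list alone). The activation and maturation list had a camera adjusted p of 0.00011 (adjusted p = 0.33 with an estimated correlation). The latter held the maturation marker CD83 (log2 fold change 2.70 ± 0.29) and the lymph node homing receptor CCR7, which stood at 28.1 ± 3.61 against 8.87 ± 2.78 CPM. Of the trafficking receptors, 10 of 22 measured members rose, 2 fell and 10 did not pass the test (10 up and 2 down when adjusted over the list alone). The trafficking receptor list had a camera adjusted p of 0.010 (adjusted p = 0.33 with an estimated correlation). CD69, which holds lymphocytes in tissue, rose by 3.66 ± 0.44 and the chemokine receptor CCR6 by 2.98 ± 0.34. Mature dendritic cell markers, which share CCR7 with these lists, rose in 3 of 5 cases (36.5 against 12.1 CPM).

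The core identity of the cells differed little in size. The sort and the naming of clusters both used identity genes, and all 14 pDC markers are in this list. Similar levels between tissues are therefore partly set by the choice of cells. In the pDC identity list 12 of 28 measured members rose, 4 fell and 12 did not pass the test (13 up and 4 down when adjusted over the list alone), with a median of 0.16. The pDC identity list had a camera adjusted p of 0.023 (adjusted p = 0.33 with an estimated correlation). CLEC4C, which encodes the sort marker BDCA2, stood at 527 ± 46.3 against 438 ± 48.0 CPM (log2 fold change 0.27 ± 0.062, adjusted p = 0.0032), and the surface receptor gene LILRA4 rose by 0.42 ± 0.073. TCL1A rose to 553 ± 212 against 226 ± 151 CPM and JCHAIN by 0.57 ± 0.082, while SCAMP5, a vesicle protein that aids cytokine secretion, stood at 77.4 ± 19.0 against 137 ± 19.2 CPM (log2 fold change -0.87). The log2 fold changes of identity genes that did not pass the test were IL3RA -0.11 ± 0.059, TCF4 0.070 ± 0.048, GZMB 0.12 ± 0.088 and IRF7 0.18 ± 0.078. Nucleic acid sensing genes went both ways, since 7 of 19 measured members rose, 3 fell and 9 did not pass the test (7 up and 3 down when adjusted over the list alone) and camera did not call the list (adjusted p = 0.074). The RNA sensor TLR7 stood at 121 ± 14.8 against 68.9 ± 9.01 CPM and the DNA sensor TLR9 rose by 0.32 ± 0.075, while TRAF6, an adaptor downstream of both, had a log2 fold change of -1.20 ± 0.10.

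Of the genes of AXL SIGLEC6 dendritic cells, a related blood subset, 6 of 12 measured members rose, 1 fell and 5 did not pass the test (7 up and 1 down when adjusted over the list alone). The AXL SIGLEC6 list had a camera adjusted p of 0.021 (adjusted p = 0.34 with an estimated correlation). CD2 stood at 61.7 ± 31.8 against 9.27 ± 7.14 CPM and SIGLEC6 rose by 1.87 ± 0.34. Over all filtered cells, where such cells were not set apart by cluster, the call of this list was lost and its direction turned (adjusted p = 0.79). In the lymphoid precursor list 7 of 14 measured members rose, 3 fell and 4 did not pass the test (7 up and 4 down when adjusted over the list alone) (camera adjusted p = 0.26), with CD38 at a log2 fold change of 1.53 ± 0.15 and IGLL1, a surrogate light chain gene of B cell precursors, at 3.76 ± 0.64. Genes of energy metabolism were higher, as 20 of 26 measured members rose, 0 fell and 6 did not pass the test (21 up and 0 down when adjusted over the list alone) in oxidative phosphorylation (camera adjusted p = 1.3e-06, and adjusted p = 0.34 with an estimated correlation) and 15 of 20 measured members rose, 0 fell and 5 did not pass the test (16 up and 0 down when adjusted over the list alone) in glycolysis. The glycolysis list had a camera adjusted p of 2.4e-05 (adjusted p = 0.33 with an estimated correlation). The glycolytic enzyme gene GAPDH stood at 517 ± 50.9 against 226 ± 16.4 CPM and the glucose transporter gene SLC2A3 rose by 3.21 ± 0.44.

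For MHC class II presentation, 11 of 15 measured members rose, 0 fell and 4 did not pass the test (11 up and 0 down when adjusted over the list alone) (camera adjusted p = 3.0e-05, and adjusted p = 0.33 with an estimated correlation), with the protease gene CTSC at a log2 fold change of 0.75 ± 0.084. In the unfolded protein response list 9 of 22 measured members rose, 0 fell and 13 did not pass the test (9 up and 0 down when adjusted over the list alone) (camera adjusted p = 0.010, and adjusted p = 0.39 with an estimated correlation), and of cytosolic ribosomal proteins 5 of 24 measured members rose, 0 fell and 19 did not pass the test (1 up and 0 down when adjusted over the list alone). The ribosomal protein list had a camera adjusted p of 0.0097 (adjusted p = 0.55 with an estimated correlation). Of glucocorticoid response genes 3 of 11 measured members rose, 3 fell and 5 did not pass the test (3 up and 4 down when adjusted over the list alone) (camera adjusted p = 0.66), with DDIT4, an inhibitor of growth signalling, at -1.41 ± 0.29. Among single genes that fell, ATP10A, a lipid flippase, stood at 33.0 ± 18.0 against 238 ± 22.1 CPM and the sorting receptor gene SORL1 (ENSG00000137642, chromosome 11, 121452203 to 121633693) at 30.6 ± 21.9 against 162 ± 34.7 CPM. The inhibitory receptor gene LILRB2 fell by 2.24 ± 0.25 on the log2 scale, and the DNA damage response gene GADD45A stood at 4.43 ± 1.64 against 21.2 ± 7.94 CPM. Every called gene described for this comparison went the same way in 6 of 6 donor pairs.

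**Figure D1:**
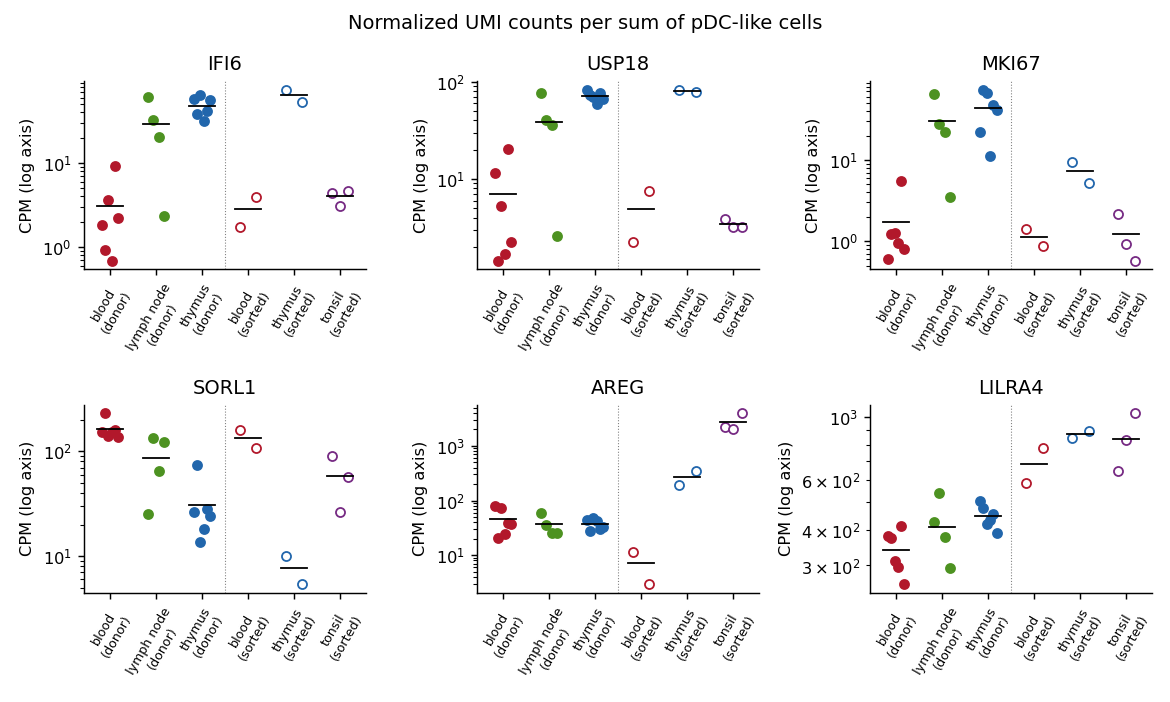
Level of 6 genes in CPM (log axis) in each summed set of pDC-like cells, by tissue, with filled points for donors, open points for sorted libraries and a line at each mean. IFI6 and USP18 were higher in thymus than in blood in both sets, SORL1 was lower, and AREG was higher in tonsil than in blood (2722 ± 1069 in tonsil and 7.19 ± 6.01 CPM in sorted blood).

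Over all genes tested by edgeR with the donor as a block, 4160 rose and 4101 fell in thymus at an adjusted p under 0.05, or 47.5% of 17397 genes. 6932 of the 8261 called genes went the same way in all 6 pairs, 1764 differed at least 2-fold, and the median absolute log2 fold change of a called gene was 0.53. Without the donor block the count was 4943 genes. Of the 40 called genes named here, 40 stayed past the test without each donor in turn.

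The lymph node was compared with blood in the same fit to ask whether a second lymphoid tissue differs from the circulation. Lymph node pDCs, from 4 donors, had higher levels of most interferon-stimulated genes and of many cell cycle and stress genes than blood pDCs in the edgeR fit. No list was called with an estimated correlation. MKI67 was 17.7-fold higher (log2 fold change 4.14 ± 0.79, adjusted p = 0.0045), at 29.9 ± 26.2 against 1.73 ± 1.87 CPM (SD, n = 4 lymph node sums and 6 blood sums). IFI6 was 11.6-fold higher, at 28.9 ± 24.4 against 3.07 ± 3.16 CPM (log2 fold change 3.53 ± 0.78, adjusted p = 0.0095). IRF4, a transcription factor of dendritic and B cells (ENSG00000137265, chromosome 6, 391739 to 411447), was 3.78-fold lower, at 165 ± 80.1 against 644 ± 137 CPM (log2 fold change -1.92 ± 0.29, adjusted p = 0.0017). These 3 genes went the same way in 4 of 4 donors. In donor 6, however, the lymph node stood close to blood, with IFI6 at 2.34 against 2.24 CPM and USP18 at 2.58 against 2.24 CPM. In that donor 78.9% of lymph node pDC-like cells lay in the cluster that held 75.6% of its blood pDC-like cells. The label and the hashtags of this donor name different tissues.

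Of the interferon-stimulated genes, 25 of 29 measured members rose, 0 fell and 4 did not pass the test (26 up and 0 down when adjusted over the list alone), with a median of 2.25. The interferon-stimulated gene list had a camera adjusted p of 1.9e-08 (adjusted p = 0.61 with an estimated correlation). USP18 rose by 2.85 ± 0.75 and TRIM22 by 0.53 ± 0.11. In G2/M phase 22 of 30 measured members rose, 0 fell and 8 did not pass the test (26 up and 0 down when adjusted over the list alone) (camera adjusted p = 2.2e-08, and adjusted p = 0.61 with an estimated correlation), with TOP2A at a log2 fold change of 2.64 ± 0.70. In S phase 12 of 25 measured members rose, 0 fell and 13 did not pass the test (13 up and 1 down when adjusted over the list alone). The S phase list had a camera adjusted p of 0.0017 (adjusted p = 0.74 with an estimated correlation). RRM2 rose by 4.32 ± 0.68, TYMS by 3.03 ± 0.62 and PCLAF, a partner of the replication clamp, by 3.64 ± 0.60. Beside these groups, 3 of 9 T cell markers rose in the lymph node sums (415 against 398 CPM), 2 of 6 B cell markers rose (497 against 322 CPM) and 1 of 2 monocyte markers rose (24.2 against 2.32 CPM).

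Among stress genes 15 of 23 measured members rose, 0 fell and 8 did not pass the test (16 up and 0 down when adjusted over the list alone). The stress gene list had a camera adjusted p of 5.5e-09 (adjusted p = 0.42 with an estimated correlation). The heat shock gene HSPA1B, whose reads are hard to tell from those of its paralog HSPA1A, had a log2 fold change of 4.73 ± 0.54, at 57.0 ± 64.3 against 9.43 ± 19.6 CPM, where donor 5, which has no lymph node sum, carried the blood mean (49.4 CPM). HSP90AA1 rose by 0.63 ± 0.081. For activation and maturation 6 of 15 measured members rose, 0 fell and 9 did not pass the test (10 up and 1 down when adjusted over the list alone) (camera adjusted p = 0.0047, and adjusted p = 0.61 with an estimated correlation), with CCR7 at 20.02 ± 3.33 against 8.87 ± 2.78 CPM. Beside this list 3 of 5 mature dendritic cell markers rose (26.5 against 12.1 CPM). Of trafficking receptors 8 of 22 measured members rose, 1 fell and 13 did not pass the test (8 up and 1 down when adjusted over the list alone) (camera adjusted p = 0.0065, and adjusted p = 0.61 with an estimated correlation), including CCR6 (log2 fold change 2.18 ± 0.41). In the NF-kB list 6 of 15 measured members rose, 2 fell and 7 did not pass the test (6 up and 2 down when adjusted over the list alone) (camera adjusted p = 0.039, and adjusted p = 0.70 with an estimated correlation), with TNFAIP8 at 0.71 ± 0.084. Of cytosolic ribosomal protein genes 0 of 24 measured members rose, 2 fell and 22 did not pass the test (0 up and 2 down when adjusted over the list alone). The ribosomal protein list had a camera adjusted p of 0.00011 (adjusted p = 0.70 with an estimated correlation). RPL3 fell by 0.22 ± 0.059 and RPL5 by 0.20 ± 0.058 on the log2 scale.

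Identity genes, many of them used to choose the cells, again differed little. Of these, 4 of 28 measured members rose, 1 fell and 23 did not pass the test (4 up and 1 down when adjusted over the list alone). CLEC4C rose by 0.23 ± 0.073 and LILRA4 by 0.27 ± 0.087, while SCAMP5 fell by 0.77 ± 0.15. Values of identity and sensing genes that did not pass the test were IL3RA -0.19 ± 0.070, TCF4 0.0074 ± 0.056, GZMB -0.17 ± 0.10, IRF7 -0.066 ± 0.093 and TLR9 0.23 ± 0.093. TLR7 rose by 0.64 ± 0.12 and TRAF6 fell by 1.04 ± 0.13. The phosphodiesterase gene PDE4D stood at 14.4 ± 7.34 against 54.4 ± 21.8 CPM. STK32B fell by 1.99 ± 0.40, the cell death activator gene BCL2L11 by 1.68 ± 0.28 and the repressor gene KLF3 by 1.59 ± 0.23. For nucleic acid sensing (median -0.028, mean 0.038) and the unfolded protein response (median -0.046, mean 0.024) the median and mean differed in sign, and camera called neither.

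edgeR called 1446 genes higher and 1657 lower in lymph node than in blood among 17397, and 2681 of these 3103 went the same way in every pair. Without donor 1 the count was 1200 genes and without donor 2 it was 1045. The count was 1353 with only the 2 groups in the fit and 1254 without the donor block, and the smallest lymph node sum (donor 4) held 112 cells. This sum stood apart from all others on the first principal component of the donor sums (113, the others at -18.5 to 16.7, 32.8% of variance). In addition, 47.1% of its hashtag calls carried more of another tag. Of the 25 called genes named here, 9 lost their call without donor 1, 8 without donor 2 and at most 4 without each of the other donors.

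The 2 solid tissues of the donors were then set against each other, to ask whether lymph node and thymus pDCs differ. edgeR called a single gene, the clone-named transcript AC023449.2, which was higher in lymph node (log2 fold change 2.32 ± 0.30, adjusted p = 0.046, 1.11 ± 0.53 against 0.208 ± 0.0554 CPM, n = 4 and 6). It falls outside the rule for named genes and was picked after its values were seen. Cell cycle genes had log2 fold changes within about 1 SE of 0, at -0.63 ± 0.70 for MKI67 and -0.62 ± 0.66 for TOP2A. The identity and sensing genes, none past the test, stood at CLEC4C -0.037 ± 0.073, IL3RA -0.080 ± 0.070, LILRA4 -0.14 ± 0.086, TCF4 -0.062 ± 0.056, GZMB -0.29 ± 0.10, IRF7 -0.25 ± 0.092, TLR7 -0.16 ± 0.11 and TLR9 -0.091 ± 0.093.

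As groups, camera placed 15 of the 17 measured lists lower in lymph node than in thymus and 0 with an estimated correlation. The donors differed here. In donor 6 lymph node stood far below thymus (IFI6 2.34 against 55.5 CPM, USP18 2.58 against 67.0 CPM), and in donor 1 it was close to it (60.3 against 57.2 and 75.6 against 82.8 CPM). The lymph node sum of donor 4 stood apart, and the label and the hashtags of donor 6 name different tissues, both as given above. Interferon-stimulated genes had a median of -0.92, with 0 of 29 members past the test (0 up and 0 down when adjusted over the list alone, camera adjusted p = 2.3e-12, and adjusted p = 0.22 with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.20 with 0 of 24 past the test (0 up and 24 down when adjusted over the list alone, camera adjusted p = 2.2e-16, and adjusted p = 0.22 with an estimated correlation). For oxidative phosphorylation the median was -0.20 (0 up and 17 down when adjusted over the list alone, camera adjusted p = 3.5e-12, and adjusted p = 0.22 with an estimated correlation), and for the NF-kB list -0.61 (0 up and 11 down when adjusted over the list alone, camera adjusted p = 1.8e-10, and adjusted p = 0.22 with an estimated correlation). MHC class II presentation had a median of -0.25 (0 up and 9 down when adjusted over the list alone, camera adjusted p = 2.4e-09, and adjusted p = 0.22 with an estimated correlation) and glycolysis one of -0.34 (0 up and 4 down when adjusted over the list alone, camera adjusted p = 1.5e-08, and adjusted p = 0.22 with an estimated correlation). The G2/M phase median was -0.43 (camera adjusted p = 7.6e-05, and adjusted p = 0.29 with an estimated correlation), the S phase median -0.069 (camera adjusted p = 0.0089, and adjusted p = 0.50 with an estimated correlation) and the stress gene median -0.50 (4 up and 8 down when adjusted over the list alone, camera adjusted p = 0.00036, and adjusted p = 0.26 with an estimated correlation). The remaining called lists were activation and maturation (camera adjusted p = 0.00017, and adjusted p = 0.22 with an estimated correlation), the unfolded protein response (camera adjusted p = 1.9e-06, and adjusted p = 0.22 with an estimated correlation), AXL SIGLEC6 genes (camera adjusted p = 0.0037, and adjusted p = 0.22 with an estimated correlation), pDC identity (camera adjusted p = 0.0097, and adjusted p = 0.26 with an estimated correlation), nucleic acid sensing (camera adjusted p = 0.017, and adjusted p = 0.22 with an estimated correlation) and the glucocorticoid response. The glucocorticoid response list had a camera adjusted p of 0.041 (adjusted p = 0.24 with an estimated correlation). Summed T cell markers stood at 415 CPM in lymph node and 476 CPM in thymus, with 0 of 9 past the test.

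At an unadjusted p under 0.05 edgeR had 2865 genes between lymph node and thymus, and DESeq2 called 187 (84 higher and 103 lower). Without donor 1 edgeR called 62 genes, and without each of the other 5 donors it called 0.

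Tonsil and blood were compared in the sorted libraries to ask how a secondary lymphoid tissue with dense lymphocyte follicles differs from blood. Tonsil pDCs had far higher levels of many immediate early and glucocorticoid-responsive genes and of some inflammatory genes. AREG, a ligand of the epidermal growth factor receptor (ENSG00000109321, chromosome 4, 74445134 to 74455009), stood at 2722 ± 1069 against 7.19 ± 6.01 CPM (SD, n = 3 and 2) and was 380.1-fold higher (log2 fold change 8.57 ± 0.84, adjusted p = 0.0053). The chemokine receptor gene CXCR4 stood at 2742 ± 671 against 122 ± 53.5 CPM (log2 fold change 4.48 ± 0.43, adjusted p = 0.0053), and GPR183, a receptor that positions cells in lymphoid tissue, at 4213 ± 1104 against 321 ± 10.4 CPM. LY6E, an interferon-induced surface protein gene, was lower, at 13.5 ± 1.21 against 48.4 ± 17.3 CPM (log2 fold change -1.84 ± 0.24, adjusted p = 0.011).

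In the stress list 11 of 25 measured members rose, 0 fell and 14 did not pass the test (25 up and 0 down when adjusted over the list alone), with a median of 3.90. The stress gene list had a camera adjusted p of 1.3e-28 (adjusted p = 0.27 with an estimated correlation). JUNB stood at 1415 ± 56.0 against 87.5 ± 15.3 CPM, ATF3 rose by 6.54 ± 0.62, NR4A2 by 6.94 ± 0.81 and HSPA1B by 8.82 ± 1.07. Outside the list, the nuclear receptor gene NR4A3 rose by 8.38 ± 0.87. Of glucocorticoid response genes 8 of 10 measured members rose, 0 fell and 2 did not pass the test (9 up and 0 down when adjusted over the list alone). The glucocorticoid response list had a camera adjusted p of 4.7e-16 (adjusted p = 0.073 with an estimated correlation). SGK1, a kinase gene induced by glucocorticoids, stood at 44.4 ± 5.91 against 0.598 ± 0.0337 CPM, and the clock gene PER1 rose by 3.84 ± 0.39. In the NF-kB list 4 of 17 measured members rose, 0 fell and 13 did not pass the test (13 up and 0 down when adjusted over the list alone) (camera adjusted p = 3.4e-08, and adjusted p = 0.53 with an estimated correlation), with PMAIP1, a cell death gene, at 5.22 ± 0.74, and the chemokine gene CXCL2, outside it, at 9.08 ± 1.54. For activation and maturation 3 of 15 measured members rose, 0 fell and 12 did not pass the test (7 up and 0 down when adjusted over the list alone) (camera adjusted p = 3.3e-05, and adjusted p = 0.27 with an estimated correlation), including CD83 (6.55 ± 0.91) and BIRC3 (4.03 ± 0.67). Among these lists CXCR4 and DUSP1 each belong to more than 1. CD69 stood at 167 ± 123 against 0.272 ± 0.0922 CPM. Summed B cell markers were at 173 CPM in tonsil and 64.7 CPM in blood (1 of 8 rose), conventional dendritic cell markers at 66.9 and 209.9 CPM (0 of 4 past the test).

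Interferon-stimulated genes moved both ways: 1 of 29 measured members rose, 2 fell and 26 did not pass the test (3 up and 7 down when adjusted over the list alone), with a median of 0.030 and a mean of -0.0029 (camera adjusted p = 0.44). Of the type I and III interferon genes 1 was measured, and it did not pass the test. IFIT2 rose by 2.47 ± 0.49 and IFI44L fell by 1.73 ± 0.33. The unfolded protein response list had 0 of 22 members past the test (camera adjusted p = 0.048, and adjusted p = 0.80 with an estimated correlation) and the ribosomal list 0 of 24. The ribosomal protein list had a camera adjusted p of 0.048 (adjusted p = 0.80 with an estimated correlation). CD2 fell by 1.34 ± 0.23, CUEDC1 by 1.55 ± 0.20 and the phosphatase gene PPM1J by 1.40 ± 0.16, while PFKFB3, a regulator of glycolysis, rose by 4.33 ± 0.25. In the glycolysis list the median was -0.15 and the mean 0.24, and camera did not call it. Identity, sensing and cell cycle genes did not pass the test, with log2 fold changes of CLEC4C -0.49 ± 0.21, IL3RA 0.046 ± 0.32, LILRA4 0.29 ± 0.27, TCF4 -0.23 ± 0.24, GZMB -0.093 ± 0.38, IRF7 -0.028 ± 0.27, TLR7 0.15 ± 0.18, TLR9 -0.34 ± 0.21, MKI67 0.11 ± 0.57 and TOP2A 0.82 ± 0.51.

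edgeR called 271 genes higher and 42 lower in tonsil among 16411, and 298 of the 313 differed at least 2-fold. Labelled batch 2 held 1 tonsil and 1 blood library. Between them 260 of the 313 called genes differed at least 2-fold (median log2 ratio 1.65). Unlike in edgeR, 1 was added to each CPM, shrinking ratios at low levels. Both libraries entered the call, which fixes the genes' direction, so this is no separate batch check. Log2 ratios of AREG, CXCR4, GPR183, JUNB and CD69 were 9.97, 4.44, 3.85, 3.79 and 5.44. Batch 1 held tonsil libraries only. The count fell to 21 without blood library 1, 47 without blood library 2, 192 without tonsil library 1 and 186 without tonsil library 2, and rose to 958 without the low-count filter and 985 with DESeq2. Of the 22 called genes named here, 18 lost their call without blood library 1, 14 without blood library 2 and 2 to 4 without a tonsil library.

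Tonsil was set against thymus to compare the lymphoid tissues of the sorted libraries. Interferon-stimulated genes were far lower in tonsil, as were a few cell cycle genes. IFI27 was 84.4-fold lower (log2 fold change -6.40 ± 0.61, adjusted p = 0.0031), at 2.15 ± 1.16 against 181 ± 56.4 CPM (SD, n = 3 and 2), and USP18 was 23.2-fold lower, at 3.42 ± 0.368 against 79.4 ± 2.47 CPM (log2 fold change -4.54 ± 0.43, adjusted p = 0.0031). CD2, an adhesion receptor gene (ENSG00000116824, chromosome 1, 116754385 to 116769228), stood at 3.15 ± 0.718 against 110.0 ± 13.6 CPM (log2 fold change -5.12 ± 0.24, adjusted p = 0.00029). VIPR2, a receptor for vasoactive intestinal peptide, was 10.2-fold higher in tonsil, at 45.8 ± 7.94 against 4.50 ± 0.0112 CPM (log2 fold change 3.35 ± 0.21, adjusted p = 0.00054).

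Of the interferon-stimulated genes 0 of 29 measured members rose, 24 fell and 5 did not pass the test (0 up and 27 down when adjusted over the list alone), with a median of -3.09. The interferon-stimulated gene list had a camera adjusted p of 1.0e-40 (adjusted p = 0.11 with an estimated correlation). RSAD2 fell by 4.42 ± 0.60, IFI44L by 4.25 ± 0.35 and LY6E by 4.57 ± 0.25. Outside the list, MNDA fell by 6.04 ± 0.82. In G2/M phase 0 of 30 measured members rose, 5 fell and 25 did not pass the test (0 up and 22 down when adjusted over the list alone) (camera adjusted p = 5.3e-21, and adjusted p = 0.11 with an estimated correlation), with UBE2C at -4.37 ± 0.43, TOP2A at -2.55 ± 0.48 and MKI67, which did not pass the test, at -2.61 ± 0.55. In S phase 0 of 25 measured members rose, 3 fell and 22 did not pass the test (0 up and 5 down when adjusted over the list alone) (camera adjusted p = 1.2e-05, and adjusted p = 0.11 with an estimated correlation), with TYMS at -2.85 ± 0.38. For activation and maturation 0 of 15 measured members rose, 3 fell and 12 did not pass the test (0 up and 7 down when adjusted over the list alone) (camera adjusted p = 0.00054, and adjusted p = 0.19 with an estimated correlation), including the death ligand gene TNFSF10 (-3.25 ± 0.30). Mature dendritic cell markers were at 34.3 CPM in tonsil and 80.3 CPM in thymus, and 2 of 5 fell.

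Some glucocorticoid response genes went the other way, as 4 of 10 measured members rose, 0 fell and 6 did not pass the test (5 up and 0 down when adjusted over the list alone). The glucocorticoid response list had a camera adjusted p of 3.1e-06 (adjusted p = 0.11 with an estimated correlation). SGK1 rose by 3.45 ± 0.47, DDIT4 by 3.33 ± 0.44 and the transcription factor gene KLF9 by 2.28 ± 0.22. SORL1 stood at 57.9 ± 32.0 against 7.71 ± 3.30 CPM (log2 fold change 2.88 ± 0.54, adjusted p = 0.039), and LILRB2 rose by 2.86 ± 0.55, BCL2L11 by 3.17 ± 0.45, CDK5R1 by 3.01 ± 0.33 and AREG by 3.33 ± 0.65. In glycolysis 0 of 20 measured members rose, 2 fell and 18 did not pass the test (1 up and 6 down when adjusted over the list alone) (camera adjusted p = 0.00023, and adjusted p = 0.11 with an estimated correlation), with SLC2A3 at -2.78 ± 0.46 and GAPDH at -1.34 ± 0.25. Camera also placed oxidative phosphorylation (camera adjusted p = 0.00074, and adjusted p = 0.74 with an estimated correlation), ribosomal proteins (camera adjusted p = 0.012, and adjusted p = 0.78 with an estimated correlation), nucleic acid sensing (camera adjusted p = 0.021, and adjusted p = 0.16 with an estimated correlation) and AXL SIGLEC6 genes (camera adjusted p = 0.011, and adjusted p = 0.27 with an estimated correlation) lower in tonsil, with 0, 0, 0 and 1 members past the test. Over all filtered cells the AXL SIGLEC6 call was lost and its direction turned (adjusted p = 0.745). CCR6 fell by 2.25 ± 0.44 and the T and NK cell receptor gene CD7 by 2.71 ± 0.22. Identity and sensing genes that did not pass the test stood at CLEC4C -0.26 ± 0.22, IL3RA 0.23 ± 0.32, LILRA4 -0.058 ± 0.27, TCF4 -0.075 ± 0.24, GZMB 0.27 ± 0.38, IRF7 -0.25 ± 0.27, TLR7 -0.50 ± 0.18 and TLR9 -0.24 ± 0.21.

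edgeR called 116 genes higher and 205 lower in tonsil than in thymus. Without thymus library 1 the count was 71, without thymus library 2 it was 107, and without tonsil libraries 1 and 2 in turn it was 156 and 160. It was 851 without the low-count filter and 899 with DESeq2, and no batch holds both tissues, since the labels give thymus none. Of the 24 called genes named here, 12 lost their call without thymus library 1, 9 without thymus library 2 and 4 to 7 without a tonsil library.

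The sorted libraries also allowed thymus and blood to be compared in samples that share no library with the donors. Sorted thymus pDCs had higher levels of most interferon-stimulated genes, of many stress and activation genes and of some cell cycle genes than sorted blood pDCs. IFI6 was 22.5-fold higher, at 63.9 ± 15.2 against 2.82 ± 1.52 CPM (SD, n = 2 and 2, log2 fold change 4.49 ± 0.42, adjusted p = 0.0033), and IFI27 stood at 181 ± 56.4 against 0.805 ± 0.747 CPM. CD2 rose by 3.78 ± 0.27 (adjusted p = 0.0012). SORL1 was 17.0-fold lower, at 7.71 ± 3.30 against 134 ± 36.9 CPM (log2 fold change -4.09 ± 0.59, adjusted p = 0.011), and ATP10A fell by 3.44 ± 0.40.

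Of the interferon-stimulated genes 25 of 29 measured members rose, 0 fell and 4 did not pass the test (28 up and 0 down when adjusted over the list alone), with a median of 2.49. The interferon-stimulated gene list had a camera adjusted p of 9.1e-32 (adjusted p = 0.13 with an estimated correlation). LY6E rose by 2.73 ± 0.28 and PARP9 by 2.78 ± 0.19. In the stress list 14 of 25 measured members rose, 0 fell and 11 did not pass the test (22 up and 0 down when adjusted over the list alone), with a median of 4.15. The stress gene list had a camera adjusted p of 3.4e-22 (adjusted p = 0.16 with an estimated correlation). JUNB rose by 4.92 ± 0.40 and ATF3 by 7.44 ± 0.65, as did NR4A3, outside the list, by 8.57 ± 0.88. For activation and maturation 8 of 15 measured members rose, 0 fell and 7 did not pass the test (11 up and 0 down when adjusted over the list alone) (camera adjusted p = 1.4e-09, and adjusted p = 0.13 with an estimated correlation), including CD83 (7.70 ± 0.98), CCR7 (2.21 ± 0.38) and TNFSF10 (3.35 ± 0.35). Mature dendritic cell markers rose in 3 of 5 cases beside these (80.3 against 15.3 CPM), and conventional dendritic cell markers were at 30.9 against 209.9 CPM (0 of 4 past the test). B cell markers were at 219 against 64.7 CPM, NK cell markers at 53.0 against 20.2, monocyte markers at 9.88 against 2.09 and platelet markers at 39.8 against 11.0 CPM, with 1 marker of each past the test. In the NF-kB list 4 of 17 measured members rose, 0 fell and 13 did not pass the test (12 up and 0 down when adjusted over the list alone) (camera adjusted p = 3.8e-08, and adjusted p = 0.26 with an estimated correlation), with SAT1 at 2.41 ± 0.27. Of trafficking receptors 7 of 23 measured members rose, 0 fell and 16 did not pass the test (8 up and 0 down when adjusted over the list alone). The trafficking receptor list had a camera adjusted p of 0.016 (adjusted p = 0.16 with an estimated correlation). CD69 was at 835 ± 789 against 0.272 ± 0.0922 CPM, and CXCR4 rose by 3.70 ± 0.43 and GPR183 by 3.48 ± 0.36.

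In G2/M phase 9 of 30 measured members rose, 0 fell and 21 did not pass the test (20 up and 0 down when adjusted over the list alone). The G2/M phase list had a camera adjusted p of 1.2e-17 (adjusted p = 0.16 with an estimated correlation). UBE2C rose by 4.27 ± 0.50 and TOP2A by 3.37 ± 0.58, while MKI67 was at 7.40 ± 3.03 against 1.13 ± 0.384 CPM (adjusted p = 0.059). In S phase 3 of 25 measured members rose, 0 fell and 22 did not pass the test (5 up and 0 down when adjusted over the list alone) (camera adjusted p = 0.0012, and adjusted p = 0.16 with an estimated correlation), in glycolysis 2 of 20 measured members rose, 0 fell and 18 did not pass the test (3 up and 0 down when adjusted over the list alone) (camera adjusted p = 0.0011, and adjusted p = 0.16 with an estimated correlation) and in the glucocorticoid list 4 of 10 measured members rose, 0 fell and 6 did not pass the test (5 up and 1 down when adjusted over the list alone). The glucocorticoid response list had a camera adjusted p of 0.00068 (adjusted p = 0.16 with an estimated correlation). SLC2A3 rose by 4.82 ± 0.59, PFKFB3 by 3.46 ± 0.25 and CD7 by 2.31 ± 0.25. Of the AXL SIGLEC6 genes 1 of 12 measured members rose, 0 fell and 11 did not pass the test (4 up and 1 down when adjusted over the list alone). The AXL SIGLEC6 list had a camera adjusted p of 0.021 (adjusted p = 0.26 with an estimated correlation). Here too the call was lost and the direction turned over all filtered cells (adjusted p = 0.250). VIPR2 fell by 2.53 ± 0.21 and CUEDC1 by 2.40 ± 0.23. Values that did not pass the test were CLEC4C -0.24 ± 0.24, IL3RA -0.18 ± 0.35, LILRA4 0.35 ± 0.29, TCF4 -0.15 ± 0.26, GZMB -0.36 ± 0.41, IRF7 0.23 ± 0.30, TLR7 0.65 ± 0.20 and TLR9 -0.094 ± 0.23.

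edgeR called 446 genes higher and 150 lower in sorted thymus than in sorted blood. Without blood library 1 the count was 68, without blood library 2 it was 254 and without thymus library 2 it was 198. It was 1465 without the low-count filter and 1523 with DESeq2, and no labelled batch holds both tissues. Of the 24 called genes named here, 12 lost their call without blood library 1 and 1 or 2 without each of the other libraries.

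**Figure D2:**
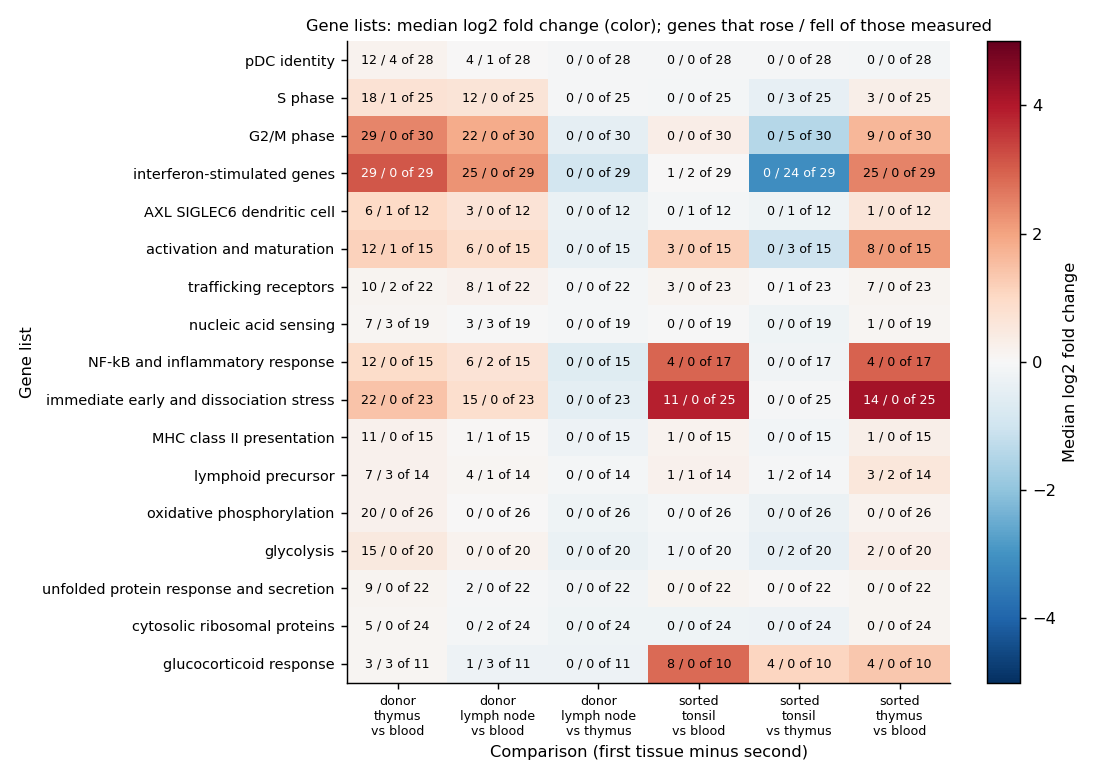
Median log2 fold change of each fixed gene list (rows) in the 6 tissue comparisons (columns), with the number of members that rose and fell of those measured written in each cell. Interferon-stimulated genes had medians of 3.12 and 2.49 for thymus against blood in donors and sorted libraries, and 0.030 for tonsil against blood.

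The differences of thymus from blood were compared between donors and sorted libraries, which share no library. The sets were counted with different Cell Ranger versions, and whether intron reads were included is not given in the sources used here. Levels may differ between the sets for that reason. Across 15095 genes tested in both, Pearson's r of the log2 fold changes was 0.659 and Spearman's rho 0.570, where genes are not independent replicates. Of 7495 genes called in the donors, 81.0% had the same sign in the sorted libraries (r = 0.746). 481 genes were called in both sets, of which 465 went the same way and 16 the opposite way. 346 rose in both, where independent calls would give 109, and 119 fell in both, where they would give 34.0.

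A cycling cell was defined as a pDC-like cell with at least 3 of 20 fixed cycling genes after thinning to 2000 UMIs. In the donors, 2.86 ± 1.52% of thymic and 0.404 ± 0.862% of blood pDC-like cells were cycling (SD, n = 6), higher in thymus in 6 of 6 donors (difference 2.46 points, exact two-sided sign-flip permutation p = 0.03125, the smallest that 6 pairs allow, and 0.1875 after Benjamini-Hochberg adjustment over the 6 tissue comparisons). In blood, donor 5 stood at 2.16% (32 of 1480 cells, Wilson 95% interval 1.54 to 3.04%), and the other 5 donors between 0 and 0.0910%. In lymph node the share was 2.35 ± 2.09%, against 0.0434 ± 0.0502% in blood of the same 4 donors (4 of 4 higher, exact permutation p = 0.125, the smallest possible, adjusted 0.25) and 2.11 ± 1.02% in their thymus (exact permutation p = 0.875). The difference from blood was 2.31 points, and 1.31 without donor 1. In the sorted libraries 0.316 ± 0.0820% of thymic and 0.0217 ± 0.0236% of tonsil cells were cycling, and in blood 0 of 2526 and 0 of 5222 cells, which allows shares of up to 0.119% and 0.0574%. These designs cannot reach an exact p under 0.1 (tonsil and a second tissue) or 0.333 (thymus and blood). Without thinning, shares were 6.24 ± 2.84% in thymus and 3.19 ± 2.32% in blood of the donors, and 1.53 ± 0.913% in thymus, 0.923 ± 0.71% in blood and 0.245 ± 0.232% in tonsil of the sorted libraries, so that tonsil then lay below blood. Thinning left out 0 to 49 cells per donor set and 0 to 174 per sorted library as too shallow.

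Free RNA in droplets can give such counts, so the share was also measured in other classes. Of AXL SIGLEC6 dendritic cell-like cells 0 of 1250 were cycling (up to 0.24%, median 14181 UMIs), of T cell-like cells 9 of 123 (7.32%, median 4420 UMIs), and of all pDC-like cells 771 of 85688 (0.900%, median 10846 UMIs). A UMI of MKI67 was found in 0.32%, 5.69% and 0.745% of these classes in turn. The AXL SIGLEC6 class holds 511 and 164 cells of sorted blood, where 0 pDC-like cells cycled. Its limit is thus no background for donor blood. There donors 2, 3 and 4 had 0.0826 to 0.0910%. In donors 1 and 6, 0 of 347 and 0 of 917 allow up to 0.865% and 0.327%. Free RNA as a source of some calls stays open, and intervals and limits cover counting error only.

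**Figure D3:**
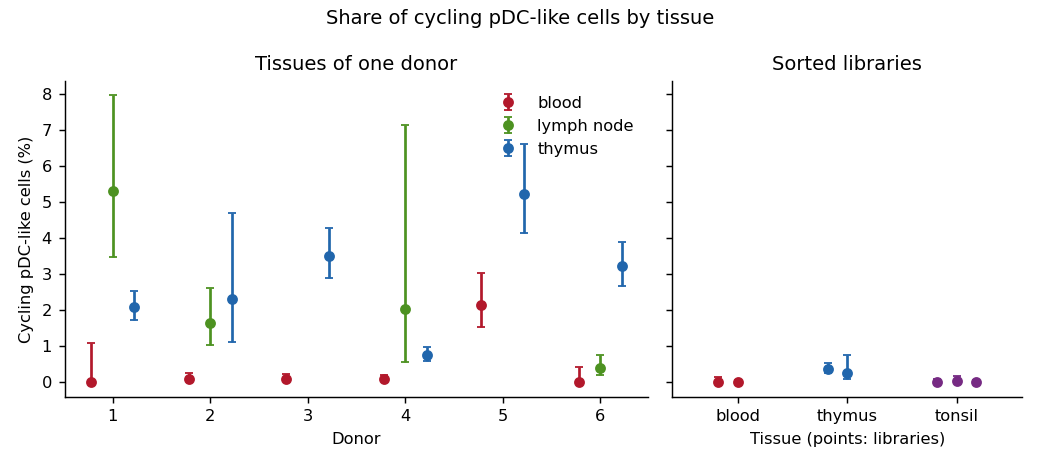
Percent of pDC-like cells with at least 3 cycling genes after thinning to 2000 UMIs, for each donor and tissue (left) and each sorted library (right), with Wilson 95% intervals. Thymus lay above blood in 6 of 6 donors, and the sorted blood libraries were at 0 of 2526 and 0 of 5222 cells.

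Cells with at least 3 of 9 AXL SIGLEC6 genes made up 0.449 ± 0.172% of thymic and 0.194 ± 0.129% of blood pDC-like cells in the donors (6 of 6 higher in thymus, difference 0.255 points, exact permutation p = 0.03125, adjusted 0.1875). After thinning to 1000 UMIs the difference was 0.0563 points, with 4 donors higher and 1 lower (exact permutation p = 0.44). With 2 or more genes 4 were higher and 2 lower. Over all filtered cells the difference turned to -0.487 points, since the cells set apart as AXL SIGLEC6 dendritic cell-like were then counted. Without thinning the shares were 22.6 ± 5.68% and 14.05 ± 7.52%. In the class itself 32.9% of cells met the rule, against 0.361% of all pDC-like cells. The share in sorted libraries was 0.777 ± 0.693% in blood, 0.319 ± 0.0356% in thymus and 0.399 ± 0.147% in tonsil, and 0.398 ± 0.420% in donor lymph node.

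pDC-like cells made up 99.5 ± 0.322% of filtered cells in donor thymus and 95.4 ± 2.53% in donor blood (6 of 6 higher in thymus, exact permutation p = 0.03125, adjusted 0.1875). In lymph node they were 92.3 ± 7.25%, against 95.2 ± 3.09% in blood (difference -2.89 points, exact permutation p = 0.62) and 99.4 ± 0.350% in the thymus of the same 4 donors (0 of 4 higher, exact permutation p = 0.125, the smallest possible). Sorted libraries held 99.7 ± 0.0578% in thymus, 96.3 ± 2.82% in tonsil and 89.6 ± 10.3% in blood. In blood library 1 the share was 82.3%, and 16.7% of its cells were AXL SIGLEC6 dendritic cell-like.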

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

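The tests of explanations here, other than that of 1 small cluster of interferon-stimulated cells, were chosen after the result was seen.

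In 136 groups of donor values, 23 held a sample far from the others, where chance gives about 1 in 20 groups. 14 of the 23 were blood of donor 5. In it CD69 stood at 23.6 CPM (the other donors at 0.781 to 4.00), HSPA1B at 49.4, IFI6 at 9.17, IFITM1 at 2.68, IGLL1 at 9.46, JUN at 182, MKI67 at 5.50, PCLAF at 6.28, RRM2 at 4.45, TCL1A at 522, TYMS at 5.15 and UBE2C at 6.35 CPM, each the highest. ATP10A was lowest, at 195 CPM (the others at 239 to 260.4), and 2.16% of cells were cycling. With the ratio rule, which drops cells with much of a second tag, 0 of 826 cells cycled. 5 of these 13 genes lay outside the range of the others. HSPA1B (5.11 CPM), RRM2 (0.889) and TCL1A (375) were still above, ATP10A (274) now above and MKI67 now below. With the main calls, 45.6% of the 1742 blood cells carried more of another tag. The cluster of 86.1% of donor 5 thymus pDC-like cells held 39.7% of the blood ones. These values go with thymus cells among its blood calls, a candidate explanation. It stays open for the 5 genes, as does a donor difference, not tested. The label and hashtags also differ in tissue.

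Interferon-stimulated genes were higher in thymus than in blood in both sets, with medians of 3.12 in donors and 2.49 in sorted libraries. Handling of dissociated tissue as the whole cause is argued against by tonsil, also a solid tissue, whose median against blood was 0.0299. With the ratio rule for hashtags the median was 3.70. Cells mixed between 2 tissues lessen the difference between them, so this rule could not decide on mixed calls as a cause. The sorted libraries carry no hashtags. A single small cluster of such cells is argued against by the median of 3.04 without its cells. A tissue difference stays open as a hypothesis and was not tested apart from other differences between thymus and tonsil samples, such as donors.

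Stress genes past the test were all above blood. These were 11 of 25 (tonsil), 14 of 25 (sorted thymus), 22 of 23 (donor thymus) and 15 of 23 (lymph node). The lowest of the 4 medians was 0.840. Since blood alone needs no dissociation, handling of solid tissue and a tissue difference cannot be told apart. A few stressed libraries as the source are argued against, since the lowest tonsil or thymus library had 3.65 times the summed level of the highest blood library. Summed CPM in the sorted libraries was 3949 and 3829 in blood, 15244 and 45184 in thymus and 39169, 27630 and 14424 in tonsil.

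Exchanging blood and thymus within donors gave 32 groupings, of which 1, the real one, called as many as 8801 genes in a fit of the 2 groups alone, and the highest other called 0. A share of 1 in 32, the smallest that these groupings allow, lies under 0.05 but does not exclude chance. Swapped pairs also add the tissue difference to the spread, which by itself lowers their counts. For lymph node and blood 4 pairs give 8 groupings, too few for a share under 0.05, with 1353 genes for the real one (1 of 8 as large) and 0 for the highest other. For lymph node and thymus the real count was 0 and the highest other 10, and 8 of 8 groupings gave as many, again too few groupings.

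Further samples far from their group were GADD45A in blood of donor 1 (36.6 CPM, highest) and SORL1 in donor 2, highest both in blood (231 CPM) and in thymus (73.9 CPM). In thymus of donor 2 IFITM1 (71.4 CPM) and IRF7 (939 CPM) were highest, and in thymus of donor 4 SCAMP5 (39.8 CPM) was lowest. In lymph node HSP90AA1 was highest in donor 2 (939.6 CPM) and TRIM22 lowest in donor 6 (159 CPM), and the AXL SIGLEC6 share was highest in donor 4 (1.02%, 1 of 98 cells).

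For thymus against blood, 2 of the genes described went one way in 6 of 6 donor pairs and the other way, without overlap, in the sorted libraries. CLEC4C was at 0.27 in donors and -0.24 in sorted libraries, and GADD45A at -2.30 and 0.88. The difference was not tested. Among all genes, 4161 moved one way in 6 of 6 pairs and did not overlap in the sorted libraries, where 2 against 2 libraries fail to overlap by chance in 33.3% of cases. Of these, 501 went opposite ways, and independent directions in the 2 sets would give 2071.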

How the results depend on the processing

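The alternatives added after the data were seen are the ratio rule in the donors, the lists and AXL SIGLEC6 share over all filtered cells, the fits without donors whose label and hashtags differ, the crossed pairing and the batch 2 pair, and the cause of a change was not tested unless given.

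Counts of called genes were within 1.5 times of the reported count under RLE factors and the stricter cell filter in all 6 comparisons. For thymus against blood in donors the count left that range only without the replicate block (4943), and the leave-one-out range was 6584 to 7741. For lymph node against blood it was 1353 with only the 2 groups and 1254 with no replicate block, and 1045 to 3830 with 1 donor left out. For lymph node against thymus, where 1 gene was called, the count was 136 without the low-count filter, 187 with DESeq2, 3 without cycling cells, 2 with MULTIseqDemux, and 0 with only the 2 groups, with Scrublet-ranked cells kept, over all filtered cells, with the ratio rule and without the donors whose label and hashtags differ (883 genes at an unadjusted p under 0.05). It was 0 to 62 with 1 donor left out. For tonsil against blood it was 958 without the filter, 985 with DESeq2 and 195 with the replicate block, and 21 to 312 with 1 library left out. For tonsil against thymus these were 851, 899 and 181, and 71 to 308. For sorted thymus against blood they were 1465, 1523 and 542, and 68 to 408. Crossed numbers as a block gave 1035. A left-out library that leaves 1 in a tissue is tested with the spread of the other groups.

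The labels do not say whether sorted libraries of the same number share a donor. The correlations of their deviations were -0.276 (blood and thymus, both pairs, equal by construction with 2 libraries per tissue), 0.377 (tonsil 1 and blood 1), -0.557 (thymus 1 and tonsil 1), 0.114 (thymus 2 and tonsil 2) and -0.147 (tonsil 2 and blood 2) over 5569 genes, which leaves this open. No other count moved by over 1.5 times with the block.

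The difference in cycling share (points) between thymus and blood ranged from 2.27 to 2.82 with 1 donor left out, where 5 pairs allow no p under 0.0625. Between lymph node and blood it ranged from 1.31 (without donor 1) to 2.94. Between lymph node and thymus it ranged from -0.741 to 1.27, and was -0.0101 after thinning to 1000 UMIs and -0.745 without thinning. Between tonsil and blood it was -0.678 without thinning.

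The difference in AXL SIGLEC6 share between thymus and blood in donors was 0.0563 after thinning to 1000 UMIs (4 donors higher, 1 lower), 0.955 with 2 or more genes (4 higher, 2 lower), 0.00605 with 5 or more, 0.243 with the ratio rule (5 higher, 1 lower) and -0.487 over all filtered cells, and 0.237 to 0.283 with 1 donor left out. For lymph node against blood it was 0 with 5 or more genes, 0.0533 with the ratio rule, -0.552 over all filtered cells and 0.0332 (without donor 4) to 0.366 with 1 donor left out. For lymph node against thymus it was 0.109 after thinning to 1000 UMIs, 0 with 5 or more genes and -0.222 to 0.108 with 1 donor left out. For tonsil against blood it was 0 with 5 or more genes and -0.867 to 0.112 with 1 library left out. For tonsil against thymus it was -0.0011 after thinning to 1000 UMIs, -5.74 without thinning, -1.01 with 2 or more genes, 0 with 5 or more and -0.00433 to 0.128 with 1 library left out. For sorted thymus against blood it was 0 with 5 or more genes and -0.947 to 0.0321 with 1 library left out. The difference in pDC-like share was 3.28 to 4.62 (thymus and blood), -6.06 to 0.638 (lymph node and blood) and -0.587 to 13.9 (tonsil and blood) with 1 sample left out.

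Of the lists called by camera, 0 were called with an estimated correlation in each of the 6 comparisons, and fry called 1 for lymph node against blood, 3 for lymph node against thymus and 3 for tonsil against blood. Lists that camera did not call were not carried through the alternatives. How differences of exactly 0 are labelled was changed after the first run. In camera of limma the AXL SIGLEC6 list lost its call and changed direction over all filtered cells for thymus against blood in donors (adjusted p = 0.790), tonsil against thymus (adjusted p = 0.745) and sorted thymus against blood (adjusted p = 0.250), where the cells of that class are part of the sums. Between both sets r was 0.746 over the genes called in donors.

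Of the named called genes, 36 of 40, 10 of 25, 3 of 22, 10 of 24 and 12 of 24 were called under every setting (thymus and lymph node against blood, then the sorted comparisons in order). Without cycling cells, the calls of which use these genes, values turned to -1.06 for UBE2C, -0.43 for RRM2 and -1.36 for TOP2A in thymus against blood, -0.93 for TOP2A in lymph node against blood, 0.43 for TOP2A in lymph node against thymus, -0.70 for MKI67 in tonsil against blood and -0.61 for MKI67 in sorted thymus against blood. The genes below were not called, and their sign was not set. In lymph node against blood TCF4 was at -0.0072 without the filter, -0.0019 with stricter cells, -0.0037 with no replicate block, -0.015 with the ratio rule and -0.032 to 0.051 with 1 donor left out, and IRF7 at 0.061 without the donors whose label and hashtags differ and -0.16 to 0.033. In lymph node against thymus CLEC4C was at 0.016 with no replicate block. Without the donors whose label and hashtags differ TLR9 was at 0.00020, MKI67 at 0.24 and TOP2A at 0.30, and with 1 donor left out at -0.22 to 0.0040, -1.68 to 0.34 and -1.70 to 0.28. In tonsil against blood IL3RA was at -0.17 with the replicate block and MKI67 at -0.013 over all filtered cells, and with 1 library left out IL3RA ranged from -0.21 to 0.38, GZMB from -0.46 to 0.42, IRF7 from -0.24 to 0.23 and MKI67 from -0.59 to 0.49. In tonsil against thymus, with the replicate block IL3RA was at -0.0090 and GZMB at -0.018, and with 1 library left out IL3RA ranged from -0.065 to 0.59, LILRA4 from -0.23 to 0.10, TCF4 from -0.18 to 0.033 and TLR9 from -0.49 to 0.054. In sorted thymus against blood these ranges were -0.55 to 0.16 for IL3RA, -0.73 to 0.17 for GZMB, -0.018 to 0.50 for IRF7 and -0.39 to 0.15 for TLR9.

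Depth limits the smallest sums: the lymph node sum of donor 4 held 112 cells and 840716 UMIs. In the sorted libraries, 2-fold changes were mostly missed on simulated data (6%, 8% and 2% recovered).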

Other observations

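The small class next to pDCs and the position of lymph node cells were described here after the data were seen. AXL SIGLEC6 dendritic cell-like cells, set apart by cluster, made up 16.7% of filtered cells in blood library 1, 3.04% in blood library 2 and 0 to 0.175% in the thymus and tonsil libraries, and 0.144 to 3.40% in the donor libraries. The genes that led their main cluster over the other cells included AXL, SIGLEC6, LYZ and CLEC10A, the last 2 known from monocytes and conventional dendritic cells. An unnamed cluster of 516 cells also had AXL SIGLEC6 markers in 53.4% of cells on average, but none among its top 10 genes. It held 3.61%, 5.26% and 0.673% of tonsil libraries 1 to 3 and 0 cells of the sorted blood libraries. The low share of the class in tonsil thus rests on the naming rule.

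A cluster led by MKI67, TOP2A and RRM2, held 0.451 to 2.499% of the cells of each donor library, 0.386% and 0.224% of the sorted thymus libraries, and 0 of 3068 and 0 of 5398 cells in the sorted blood libraries. Cycling genes were left out of the genes used for clustering. A cluster led by IFIT1, IFIT3 and RSAD2 held 0.195 to 2.53% of the donor libraries and 0 cells of the 7 sorted libraries.

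On an axis from blood (0) to thymus (1), built for each donor from its own blood and thymus sums over the genes called in the other donors, lymph node sums stood at 1.00, 0.70, 0.86 and 0.19 in donors 1, 2, 4 and 6. With the ratio rule they stood at 1.04, 0.71, 0.85 and 0.21, and with MULTIseqDemux at 0.93, 0.67, 0.85 and 0.20. Of the lymph node calls of donor 4, 47.1% carried more of another tag, and the label and hashtags of donor 6 differ. An earlier run tested mixed hashtag calls on this axis, and the test on donor 5 took its place.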
